A study of Homo sapiens with 12 samples.

How the data were processed

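Kidney tissue from 12 living donors was profiled on Affymetrix HG-U133A arrays, which carry 22283 probe sets and are read in a single colour. There was 1 array per donor, made from total RNA of 2 needle cores. Per the labels and the series' design text, 6 donors had laparoscopic nephrectomy and were biopsied after 2 to 3 hours of carbon dioxide pneumoperitoneum, that is, abdominal insufflation with the gas. The other 6, the controls, had open surgery and were biopsied after a flank incision with little handling of the kidney. All 12 donors were under general anaesthesia and had an induced diuresis. The groups were taken from the sample titles, so route of surgery, time under anaesthesia and pneumoperitoneum differed together between them. The arrays of a group are separate donors, and p-values therefore refer to the spread between donors, biopsy sampling and array processing together.

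The deposited table holds 1 linear signal intensity per probe set and array, made by the authors with the GeneChip Operating System (GCOS), version 1.0 per the series' design text. In the file, the mean after trimming 2% at each end was 250.08 or 250.09 on every array, so the authors' signal intensities had been scaled to a common level before deposit. Per the series' design text the authors went on to RMA Express and to class comparisons in BRB ArrayTools at p under 0.005. The deposited intensities are the GCOS signals and not RMA values, so the values here differ from those the authors tested. The table used here has no detection calls, and which probe sets lay above background is therefore unknown. Arrays give no read depth, and the precision is limited by their number.

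From these intensities, log2(signal + 16) was computed and quantile-normalized over the 12 arrays. A fold change on this scale understates changes of dim genes. The 68 control probe sets, Y-linked genes and the X-inactivation transcripts were left out of the tests. Gene names came from the platform annotation, in which 19034 probe sets had 1 gene, 1022 had several and 2107 had none named. Of the probe sets with 1 gene, 19022 were matched to a current RefSeq gene through the Entrez ID and 12 kept the annotation's name. No gene was named from a probe set with several genes. Each of the 11939 genes was represented by its probe set of highest mean over the 12 arrays, and genes at or above the 30th percentile of all probe sets were kept, which left 9321 genes. Genomic coordinates are not given, since the table names no genome build.

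The comparison was laparoscopic minus control, fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Because the design text names p under 0.005, the number of genes at that unadjusted level was added after the data had been seen, and a class comparison without variance moderation was run on the same values. Lists of genes were tested with limma's camera (preset inter-gene correlation 0.01, adjusted over 24 lists), with an estimated correlation, fry and an exact two-sided permutation test of list means beside it. The 24 lists were 15 biological programmes and 9 sets of cell type markers. Listed genes without a tested probe set stayed out. Members were also adjusted over their list alone (Benjamini-Hochberg, adjusted p under 0.05), which does not account for the 24 lists. Array quality was measured by the log2 ratio of 3' to 5' control probe sets of GAPDH and beta-actin, the median signal and the median correlation within the group, compared by exact two-sided permutation tests, whose smallest possible p with 6 against 6 arrays is 0.0022. The signals of the Alu repeat and 18S ribosomal RNA control probe sets were added after the data had been seen, as were the runs without particular arrays that stood apart, those with the GAPDH or beta-actin ratio alone or both as covariates, and the estimated correlation in runs other than the main one.

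The groups, the main fit, the lists, the alternative settings listed below and the rule for named genes were fixed before the data were examined. The rule named, in each direction, the 10 genes of largest change past the threshold, filled up with genes of smallest unadjusted p where fewer passed. From each list it named up to 4 members past the threshold, or otherwise the 2 of smallest p. KRT7, HAVCR1, LCN2, VEGFA, ADM, BNIP3L, FOS and KCNN1, outside this rule, were chosen after their values were seen. The alternatives were median centring, pseudocounts of 1 and 64, no filter or a filter at the 50th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust, array weights, the replicate number as a block, the mean 3'/5' ratio of GAPDH and beta-actin as a covariate, and leaving out each array in turn. The numbers in the titles belong to different donors in the 2 groups, so they were no block in the main fit.

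The procedure was tested on simulated data made from these arrays, with 200 of the 9321 genes changed. A log2 change of 0.5 was called in 0% of changed genes, 1 in 55.8%, 1.5 in 85.2% and 2 in 95.5%, with 8.33 to 9.33 false calls on average for the changes of 1 to 2. A simulated shift of 0.3 in all members of 1 list, the hypoxia response, was called in 20 of 20 draws, and no list was called in any of the 20 draws without a shift. The draws made genes vary independently, so they measure neither false calls nor missed shifts among correlated genes. In the real arrays the estimated correlation was -0.019 for the hypoxia response and 0.44 for the thick ascending limb list. In 62 of 99 other splits of the real arrays camera called at least 1 list, up to 8. No pair of arrays held identical values, and correlations between arrays ranged from 0.841 to 0.941.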

Results

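The study compared kidneys of living donors removed by laparoscopy with kidneys removed by open surgery, to ask which transcripts differ after hours of carbon dioxide pneumoperitoneum, the insufflation of the abdomen that laparoscopy needs. Transcript levels were measured in needle cores taken from the kidney during the operation. There were 12 arrays, 6 laparoscopic and 6 control, each from a different donor and made from 2 cores. Every array had the same trimmed mean signal, 250.08 or 250.09, and median signals ranged from 107.1 to 127.7. Values below are log2 levels after quantile normalization, given as the mean ± SD of 6 arrays, and differences are laparoscopic minus control with the standard error (SE) of the limma fit.

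The gene with the smallest p among those higher in the laparoscopic kidneys was CDKN1A, an inhibitor of cyclin-dependent kinases induced by many kinds of cell stress. Its level was 9.54 ± 0.28 (SD, n = 6) in the laparoscopic and 8.13 ± 0.46 (SD, n = 6) in the control kidneys, a difference of 1.41 (SE 0.21) or 2.66-fold, and every laparoscopic array lay above every control array. OSBPL8, a lipid transfer protein of the endoplasmic reticulum, was lower by a log2 difference of -1.14 (SE 0.18), from 10.15 ± 0.33 (SD, n = 6) in controls to 9.01 ± 0.28 (SD, n = 6), also without overlap. Neither passed the test over all genes, with a limma adjusted p of 0.122 for both.

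Of 9321 genes tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.122. There were 994 genes at an unadjusted p under 0.05, where 466 would be expected without any difference, and 150 at an unadjusted p under 0.005, where 46.6 would be expected. Of these 150 genes 79 were higher and 71 lower in the laparoscopic kidneys. The class comparison without variance moderation gave 139 genes at p under 0.005, 1001 at p under 0.05 and 0 after adjustment. The 2 groups did not overlap for 74 genes (0.794% of genes, where chance gives 0.216%).

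Without control arrays 3 to 6, which stood apart from the other arrays as described further on, 50 genes were at an unadjusted p under 0.005 in a comparison of 6 against 2 arrays, and 10 of them were among the 150. In that run 46.6 genes would be expected at that level, and 443 were at an unadjusted p under 0.05, where 466 would be expected. Fewer arrays also make fewer genes reach these levels. All 150 kept their direction there, with a median of 74.8% of the difference left, and 53 moved by over 1.5 times. The 150 had been picked with the remaining arrays among the data, which favours a kept direction. Of 66 genes named by a fixed rule, 30 had differences that moved by over 1.5 times without those 4 arrays, 25 of them nearer to 0 or reversed, and so did the means of 21 of 24 gene lists, 10 of them nearer to 0 or reversed and the others farther from 0. These values are given below, as are one or both extremes of the values that moved as much when 1 array was left out. CDKN1A and OSBPL8 passed (2 genes) with a pseudocount of 64 and with eBayes with trend and robust, BARX2 passed without laparoscopic array 3, and CR2, AGAP1 and KCNN1 passed without laparoscopic array 5.

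The other genes of smallest p that were higher in the laparoscopic kidneys came from several classes, and none of them passed. ENO1, a glycolytic enolase, differed by 0.67 (SE 0.16) with levels of 12.20 ± 0.24 and 11.52 ± 0.24, and both of its other probe sets were also higher. The transcription factor BARX2 differed by 1.40 (SE 0.26) and the corepressor TLE1 by 0.71 (SE 0.16). ST3GAL5, the synthase of ganglioside GM3, differed by 0.90 (SE 0.21) and the glycosyltransferase A4GNT by 0.89 (SE 0.20). The surface receptors FCAR, which binds IgA, and GP1BA, a platelet glycoprotein, differed by 1.21 (SE 0.25) and 0.90 (SE 0.21). ADCY8, an adenylyl cyclase, was higher by 0.78 (SE 0.17) and CACNB1, a calcium channel subunit, by 1.26 (SE 0.29). Neither of the other 2 probe sets of CACNB1 was higher, and the other probe sets of FCAR and TLE1 were split. The differences of TLE1, GP1BA, ADCY8 and CACNB1 were 0.40, 0.44, 0.48 and 0.78 without control arrays 3 to 6. BARX2, FCAR, ADCY8 and CACNB1 had mean levels below the median of all probe sets (7.02), and whether they lay above background is unknown.

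Among genes lower in the laparoscopic kidneys, none passed either. CR2, a complement receptor of B cells and follicular dendritic cells, had the largest difference of the 20 named genes, -2.50 (SE 0.56), from 8.36 ± 0.55 in controls to 5.86 ± 1.46. Laparoscopic array 5 had a control-like level of 8.36, and the difference of CR2 passed without that array (difference -3.00, limma adjusted p = 0.018). PIAS3, an inhibitor of STAT3 signalling, was lower by -1.26 (SE 0.21, limma adjusted p = 0.126) and ZNF292, a zinc finger gene, by -1.03 (SE 0.19). The RNA-binding proteins RBFOX1, a splicing regulator, and ZFP36L1, which promotes decay of AU-rich transcripts, differed by -1.15 (SE 0.23) and -1.12 (SE 0.25). Of the 3 other probe sets of ZFP36L1, 2 were also lower, and over the alternative settings its difference ranged from -1.60 to -0.14. PCYOX1, a prenylcysteine oxidase, differed by -1.21 (SE 0.25), SEMA6B, a semaphorin, by -1.20 (SE 0.26), AGAP1, a regulator of Arf proteins, by -0.86 (SE 0.18), and AK4, a mitochondrial adenylate kinase, by -0.87 (SE 0.19). The difference of PCYOX1 was -0.58 without control arrays 3 to 6. Single laparoscopic arrays lay far from the rest for ZNF292 (array 2, 6.85), AGAP1 (array 5, 8.25) and ZFP36L1 (array 5, 6.51). PIAS3, RBFOX1 and SEMA6B had mean levels below the median of all probe sets. All 20 genes, 10 in each direction, kept their direction when any 1 array was left out. Their selection by smallest p in these same arrays makes that likely.

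**Figure D1:**
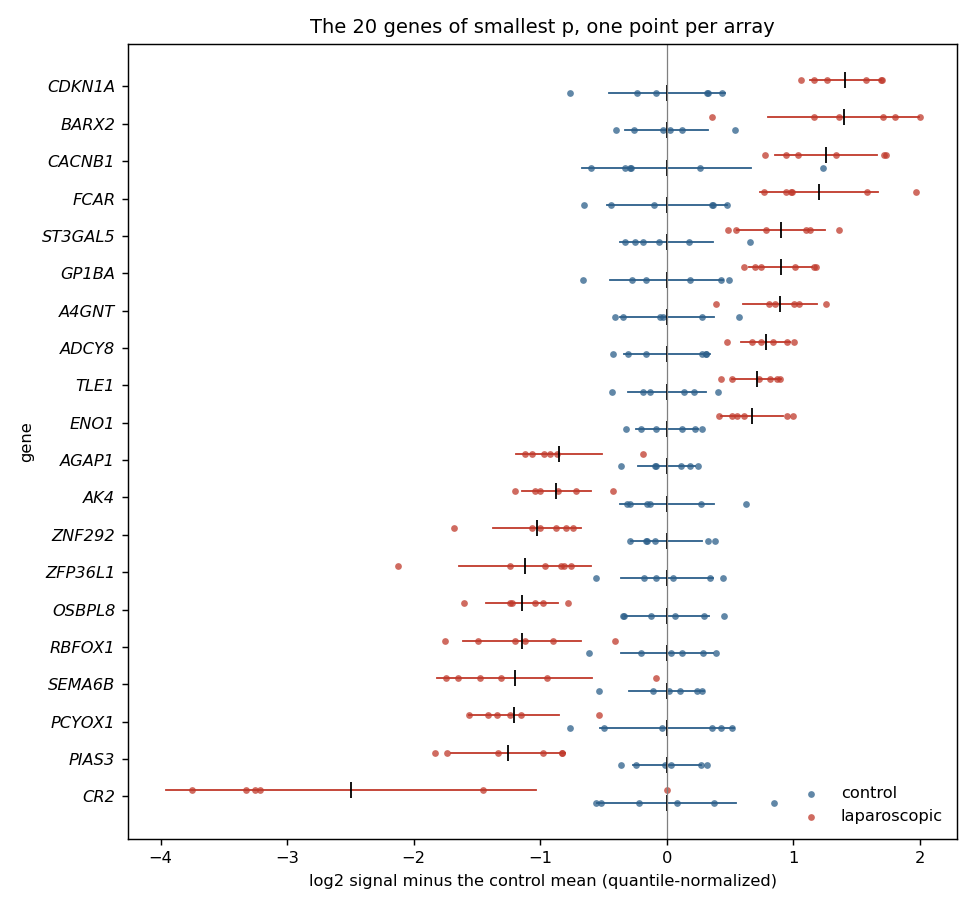
Log2 signal of each array minus the control mean (x axis) for the 20 genes of smallest p, 10 in each direction (y axis); points are arrays, vertical ticks group means and horizontal lines 1 SD. For 11 of the 20 genes the laparoscopic and control arrays do not overlap, and for CR2 1 laparoscopic array lies at the control level.

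Lists of genes fixed before the data were examined asked whether known programmes of kidney stress, metabolism and cell types differed between the groups. None of the 24 lists passed camera, an estimated correlation, fry or an exact permutation test of list means. At an unadjusted p under 0.05 there were 3 lists with camera, oxidative phosphorylation, thick ascending limb and proximal tubule, 0 with an estimated correlation and 2 with fry. Tested for change in either direction, fry passed 4 lists, which were hypoxia response (adjusted p = 0.0043), tubular injury (adjusted p = 0.0010), apoptosis (adjusted p = 0.022) and oxidative phosphorylation (adjusted p = 0.0010). That version of fry asks whether members differ at all, not whether they differ more than other genes. Since 994 of all 9321 genes were at an unadjusted limma p under 0.05, passing it does not set these lists apart. No gene of any list passed over all genes tested. Some list genes named below had mean levels below the median of all probe sets (7.02), and whether they lay above background is unknown. They include EGR3, PFKFB4, CHORDC1, IL6, TNF, XIAP, BAK1, CDH5, MS4A1, CD3E, PF4, FABP4, HAVCR1 and LCN2.

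Genes of tubular injury, which mark damaged or repairing tubule cells, had a mean difference of 0.21 (SE 0.15, camera p = 0.362 with an estimated correlation, before adjustment), with 12 of 22 members higher. Adjusted over the list alone, 3 members passed and all 3 were higher, namely CDKN1A, KRT7, an epithelial keratin (0.74, SE 0.23), and FGA, the fibrinogen alpha chain (0.71, SE 0.21). HAVCR1, the kidney injury molecule, was 6.73 ± 0.27 against 5.98 ± 0.93, and LCN2, which encodes the injury marker NGAL, was 6.53 ± 0.49 against 6.63 ± 0.42, and neither passed. Without control arrays 3 to 6 the tubular injury list passed at a mean difference of 0.41 (camera adjusted p = 0.0048), and without laparoscopic array 2 at 0.31 (adjusted p = 0.041). With an estimated correlation its p in these 2 runs was 0.117 and 0.134, before adjustment. The differences of KRT7, HAVCR1 and LCN2 were 0.29, 1.22 and -0.57 without those 4 control arrays, that of HAVCR1 was 0.47 without control array 2, and that of LCN2 lay between -0.20 (without laparoscopic array 3) and 0.038 (without laparoscopic array 2).

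Genes of oxidative phosphorylation were higher in 24 of 30 cases, with a mean difference of 0.12 (SE 0.033) and a camera adjusted p of 0.099. Its p was 0.053 with an estimated correlation, before adjustment. SDHA, the catalytic subunit of succinate dehydrogenase, differed by 0.50 (SE 0.13) and COX5B, a subunit of cytochrome c oxidase, by 0.48 (SE 0.18). The list passed under median centring, with a mean difference of 0.17 (adjusted p = 0.0071), and without laparoscopic array 2, with 0.13 (adjusted p = 0.025). With an estimated correlation its p in these 2 runs was 0.266 and 0.059, before adjustment. Fatty acid oxidation had a mean difference of -0.028 (SE 0.041). PPARA, its nuclear receptor, was lower by -0.76 (SE 0.22), with laparoscopic array 5 far below the rest of its group at 6.41 and its other probe set in the opposite direction. ACAA1, a peroxisomal thiolase, was higher by 0.35 (SE 0.16). With control arrays 3 to 6 left out, the mean of oxidative phosphorylation was 0.075 and that of fatty acid oxidation -0.062, and the differences of COX5B and PPARA were 0.075 and -0.16. The fatty acid oxidation mean was -0.050 without laparoscopic array 2 and -0.0020 without laparoscopic array 5.

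Hypoxia response genes were divided, with 12 higher and 11 lower and a mean difference of 0.093 (SE 0.062). Adjusted over the list alone, 2 passed, ENO1 and PFKFB4, a regulator of glycolysis (0.81, SE 0.22). The direct hypoxia targets VEGFA and ADM were higher by 0.23 (SE 0.20, 1 of 3 other probe sets in that direction) and 0.22 (SE 0.34), whereas BNIP3L, a mitophagy receptor, was lower by -0.50 (SE 0.16), and none of these passed. Genes of the unfolded protein response were higher in 14 of 19 cases with a mean of 0.14 (SE 0.052, camera adjusted p = 0.285). Among them the chaperones HYOU1 and HSPA5 differed by 0.48 (SE 0.15) and 0.37 (SE 0.20). Laparoscopic array 1 had a control-like HYOU1 level of 9.60, and the difference of HSPA5 turned without control arrays 3 to 6 (-0.00098). Heat shock genes had a mean difference of -0.047 (SE 0.097), with HSPH1 at -0.47 (SE 0.24) and CHORDC1 at -0.53 (SE 0.29). Antioxidant genes were lower in 14 of 17 cases with a mean of -0.10 (SE 0.098), among them GCLM at -0.60 (SE 0.33), while glutathione reductase GSR was at 0.66 (SE 0.22). With control arrays 3 to 6 left out, the means of the hypoxia, heat shock and antioxidant lists were 0.22, -0.078 and 0.015, and the differences of VEGFA, ADM, BNIP3L, HSPH1 and CHORDC1 were 0.10, 0.60, -0.15, -0.20 and -0.32. Among runs without 1 array, the heat shock mean was -0.11 without laparoscopic array 5 and -0.00031 without laparoscopic array 2, the antioxidant mean -0.16 without control array 1 and -0.052 without laparoscopic array 1, and the hypoxia mean 0.051 without control array 2. The difference of ADM was -0.090 without laparoscopic array 5, that of VEGFA 0.14 and that of HSPA5 0.22 without control array 4, that of CHORDC1 -0.31 without laparoscopic array 1, and that of GCLM -0.35 without laparoscopic array 4.

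The immediate-early genes, which respond within minutes to handling and stress, varied widely within both groups and had a mean difference of 0.17 (SE 0.31). FOS was 7.55 ± 1.84 in the laparoscopic and 8.14 ± 1.67 in the control kidneys, while EGR3 and KLF6 were higher by 0.85 (SE 0.32) and 0.81 (SE 0.36). The inflammatory NF-kB targets had a mean difference of 0.067 (SE 0.20), with IL6 at 0.59 (SE 0.28) and TNF at -0.59 (SE 0.34). IL6 and TNF were dim, and so were EGR3, XIAP and BAK1 of this paragraph. Interferon response genes had a mean of 0.019 (SE 0.064), with ISG15 at 0.63 (SE 0.19) and IFI6 at 0.55 (SE 0.22). Of the apoptosis genes 10 were higher and 11 lower, with a mean of -0.0030 (SE 0.050), with XIAP, an inhibitor of caspases, at -1.02 (SE 0.30) and BAK1, a promoter of cell death, at 1.01 (SE 0.37). The means of the immediate-early, NF-kB, interferon and apoptosis lists were 0.044, 0.17, 0.15 and -0.026 without control arrays 3 to 6, and the differences of FOS, IL6 and IFI6 were -2.21, 1.18 and 0.35. Single arrays moved these values too. The immediate-early mean was 0.031 without laparoscopic array 1 and 0.33 without control array 1, the NF-kB mean -0.048 without laparoscopic array 5 and 0.17 without laparoscopic array 3, the interferon mean -0.025 without control array 2 and 0.038 without laparoscopic array 2, and the apoptosis mean -0.033 without laparoscopic array 1 and 0.018 without laparoscopic array 3. The difference of FOS was -1.07 without laparoscopic array 6 and 0.076 without control array 1, that of IL6 0.36 without control array 2 and that of TNF -0.33 without laparoscopic array 4.

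Glucocorticoid response genes had a mean difference of 0.21 (SE 0.16). Adjusted over the list alone 1 member passed, ZBTB16, a steroid-induced transcription factor, which was 10.03 ± 0.37 against 8.96 ± 0.62. KLF9 was lower by -0.80 (SE 0.28), with neither of its other 2 probe sets in that direction, and its difference was -0.039 without control arrays 3 to 6. Acid-base transport genes, which move acid and bicarbonate, had a mean of 0.042 (SE 0.062) and a camera direction of down, with SLC4A4, the bicarbonate cotransporter, at -0.31 (SE 0.16) and carbonic anhydrase CA4 at 0.46 (SE 0.30). Circadian clock genes had a mean of -0.082 (SE 0.059) and a median of 0.011, with a camera direction of down, NFIL3 at 0.33 (SE 0.20) and HLF at -0.31 (SE 0.20). Single arrays lay far from their group for SLC4A4 (laparoscopic array 2, 12.07), CA4 (control array 1, 9.93) and NFIL3 (control array 1, 8.20). Cytosolic ribosomal protein genes had a mean of 0.037 (SE 0.032), with RPL7 at 0.23 (SE 0.13), its other probe set in the opposite direction, and RPS25 at -0.20 (SE 0.12), and under median centring the list passed at 0.14 (adjusted p = 0.045, and p = 0.435 with an estimated correlation, before adjustment). In the run without control arrays 3 to 6 the means of the glucocorticoid, acid-base, circadian and ribosomal lists were 0.49, -0.055, 0.024 and 0.0017, and the differences of SLC4A4, CA4, NFIL3 and RPL7 were 0.0014, 0.16, 0.63 and 0.46. With 1 array left out, the glucocorticoid mean was 0.11 (without control array 2), the acid-base mean 0.020 and 0.088 (without control array 6 and laparoscopic array 6), the circadian mean -0.051 (without laparoscopic array 4), the ribosomal mean 0.019 (without control array 5), and the differences of CA4 and NFIL3 0.24 and 0.19 (without laparoscopic arrays 2 and 1).

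Markers of nephron segments differed in opposite directions without passing. Proximal tubule markers were lower in 17 of 23 cases with a mean difference of -0.12 (SE 0.074, camera adjusted p = 0.183 and p = 0.218 with an estimated correlation, before adjustment). The endocytic receptor LRP2 was lower by -0.86 (SE 0.26) and the sulfate transporter SLC13A1 by -0.57 (SE 0.18). Markers of the thick ascending limb were higher in 7 of 9 cases with a mean of 0.40 (SE 0.27, camera adjusted p = 0.183 and p = 0.269 with an estimated correlation, before adjustment). Adjusted over the list alone 2 passed, SLC12A1, the furosemide-sensitive cotransporter, with 11.38 ± 0.80 against 9.84 ± 0.83, and PPP1R1A (1.33, SE 0.41). Both lists passed without laparoscopic array 2, at -0.18 and 0.53 (adjusted p = 0.020 for both), with p = 0.033 and 0.125 with an estimated correlation, before adjustment. Without laparoscopic array 4 the means were -0.070 and 0.23, and neither passed. With median centring the means were -0.060 and 0.42, and neither passed. The thick ascending limb mean was 0.096 without control arrays 3 to 6, and the differences of LRP2, SLC13A1, SLC12A1 and PPP1R1A were -0.21, -0.34, 0.80 and 0.70.

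Of the distal tubule and collecting duct markers, with a mean of 0.050 (SE 0.11), 1 passed adjusted over the list alone. This was AQP2, the vasopressin-regulated water channel, which was 10.65 ± 0.34 in the laparoscopic and 9.90 ± 0.23 in the control kidneys. The sodium channel subunit SCNN1A differed by 0.48 (SE 0.22), with 1 of its 2 other probe sets in that direction. Podocyte markers had a mean of -0.10 (SE 0.13), with WT1 at -0.55 (SE 0.32). The probe set used for PTPRO had a mean log2 level of 14.47, very bright for a podocyte gene, and its other probe set had the opposite direction from the 0.18 (SE 0.12) found. Endothelial markers had a mean of -0.083 (SE 0.047), and adjusted over the list alone 1 passed, the angiopoietin receptor TEK at 0.62 (SE 0.17), while CDH5 was at -0.65 (SE 0.23). Laparoscopic array 5 was far above the rest of its group for TEK (9.41) and control array 4 far below for CDH5 (6.15). With control arrays 3 to 6 left out, the means of the distal, podocyte and endothelial lists were 0.19, -0.014 and -0.035, and the differences of WT1, PTPRO and TEK were -0.32, 0.071 and 0.41. The podocyte mean was -0.17 without laparoscopic array 1 and -0.021 without control array 3, and the distal mean -0.0050 without laparoscopic array 4 and 0.12 without laparoscopic array 2.

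Leukocyte markers were higher in 11 of 14 cases with a mean of 0.18 (SE 0.091, camera adjusted p = 0.285), with MS4A1, a B cell marker, at 0.75 (SE 0.22) and CD3E at 0.35 (SE 0.24). Fibroblast and smooth muscle markers had a mean of -0.0078 (SE 0.13), with COL1A1 at 0.46 (SE 0.29, 2 of 3 other probe sets in that direction). POSTN was at -0.54 (SE 0.32), with laparoscopic array 2 apart at 9.03 and its other probe set in the opposite direction. The leukocyte list passed without control arrays 3 to 6 at 0.35 (adjusted p = 0.0049) and the fibroblast list at 0.32 (adjusted p = 0.021), with p = 0.0094 and 0.052 with an estimated correlation, before adjustment, and neither passed after adjustment of these. Markers of blood cells had a mean of -0.016 (SE 0.21), a median of 0.098 and a camera direction of up, with HBB at -0.93 (SE 0.66) and PF4 at -0.50 (SE 0.40). The 3 adipocyte markers had a mean of 0.18 (SE 0.18), with LPL at 0.39 (SE 0.26), its other probe set in the opposite direction, and FABP4 at 0.35 (SE 0.43). In the run without control arrays 3 to 6 the mean of the blood list was -0.38, and the differences of CD3E, POSTN, HBB, PF4, LPL and FABP4 were 0.13, 0.31, -2.95, -0.26, 0.000038 and 0.73. Single arrays mattered here as well, with a fibroblast mean of -0.084 without control array 2 and 0.060 without control array 6, a blood mean of -0.11 without control array 4 and 0.12 without control array 1, and an adipocyte mean of 0.069 without laparoscopic array 3. The differences of CD3E (0.22 without control array 5), HBB (-0.48 without control array 2), PF4 (-0.26 without laparoscopic array 3) and FABP4 (0.034 without control array 2 and 0.63 without laparoscopic array 1) moved by over 1.5 times.

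**Figure D2:**
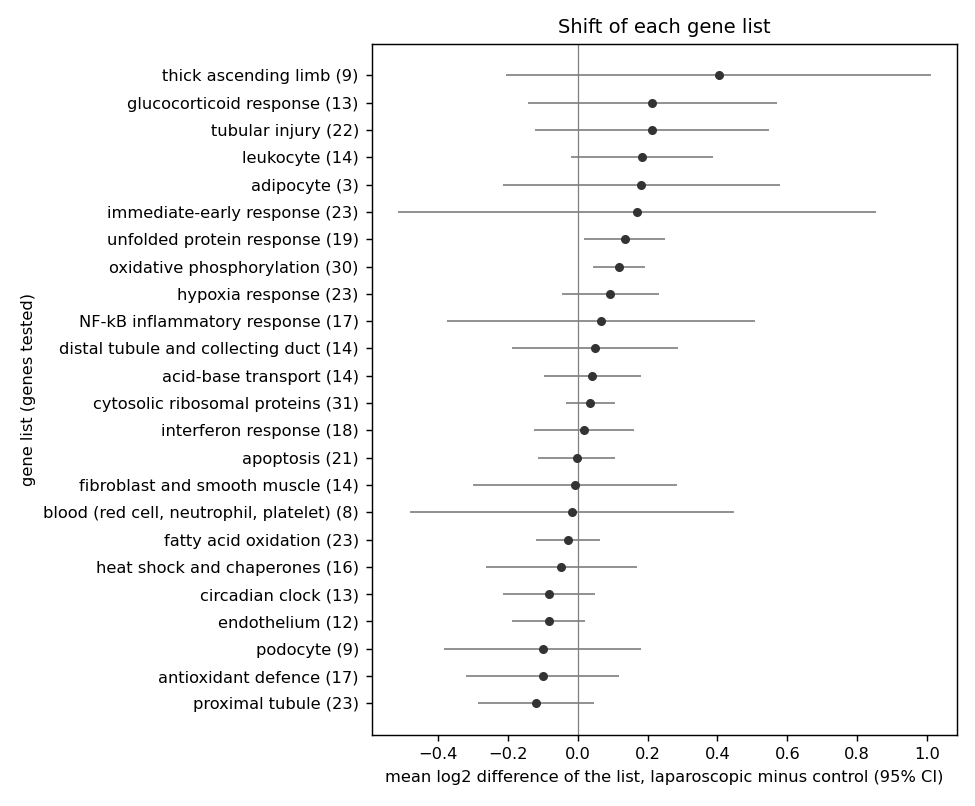
Mean log2 difference, laparoscopic minus control, of each of the 24 gene lists (x axis) with its 95% confidence interval, and the number of genes tested in parentheses (y axis). The intervals of oxidative phosphorylation (0.045 to 0.192) and of the unfolded protein response (0.019 to 0.251) lie above 0, and no list passed after adjustment over the 24 lists.

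The arrays did not divide by group alone. Control arrays 3 to 6 correlated with each other at 0.901 to 0.920 on average and less with the laparoscopic arrays (0.873 to 0.901), while control arrays 1 and 2 lay among the laparoscopic arrays on the first principal component, at -7.78 and -3.66, against 15.9 to 30.2 for control arrays 3 to 6. Among measures of RNA and array quality, the log2 3'/5' ratio of GAPDH was 0.88 ± 0.10 (SD, n = 6) in laparoscopic and 0.62 ± 0.28 (SD, n = 6) in control arrays (exact permutation p = 0.061, adjusted p = 0.15). That of beta-actin was 0.66 ± 0.18 against 0.90 ± 0.12, the opposite direction (exact permutation p = 0.026, adjusted p = 0.15). The signal of the Alu repeat control probe set was 37478 ± 3745 against 30020 ± 7932 (exact permutation p = 0.076, adjusted p = 0.15), and control arrays 3 to 6 ranged from 21020 to 31916. Median signal (exact permutation p = 0.85), correlation within the group (exact permutation p = 0.90) and 18S ribosomal RNA signal (exact permutation p = 0.87) did not differ by more than the spread between arrays.

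**Figure D3:**
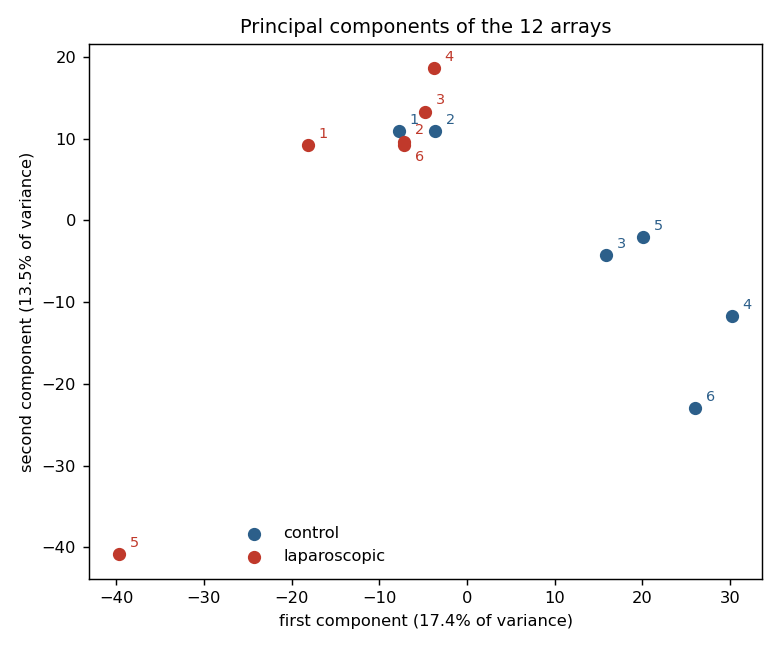
First and second principal component of the 12 arrays over the tested genes, with 17.4% and 13.5% of the variance; numbers are replicate numbers and colours the groups. Control arrays 3 to 6 lie to the right (15.9 to 30.2), control arrays 1 and 2 lie with the laparoscopic arrays, and laparoscopic array 5 lies alone at -39.6 and -40.9.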

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

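The count at unadjusted p under 0.005, the runs without particular arrays, the number of other splits with a list past the threshold and the test with the 3'/5' ratios were chosen after the result was seen. The other tests were written down beforehand.

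Among 100 splits of the 12 arrays only 1, the real one, gave as many as the 150 genes at an unadjusted p under 0.005. Random groupings thus rarely gave as many, but the highest other count, 134, came from 1 of the 5 other splits that kept control arrays 3 to 6 together. Those 5 splits had a median of 126 genes, against 37 over all other splits, which points to a structure of the arrays. They are too few to tell the real count apart from a random grouping that keeps control arrays 3 to 6 together. With the GAPDH or beta-actin 3'/5' ratio as covariate, medians of 93.7% and 105% of the 150 genes' group differences were left. This argues against a trend with either ratio alone as the whole cause, but only weakly. The 150 genes had been picked for their group difference in these same arrays, which favours a large share left. Both ratios also moved with the group (correlations 0.57 and -0.66). Wider SEs (median 0.21 before, 0.26 and 0.28 after) left only 33 and 42 of the genes at that level. With both ratios together a median of 91.5% was left, with 13 of the genes at that level. What stays open is that many of these genes may reflect what sets control arrays 3 to 6 apart: genes picked in 3 laparoscopic arrays against those 4 lay in the same direction in the held-out arrays, the 3 other laparoscopic against control arrays 1 and 2, in 47.6% to 61.8% of cases over 20 choices of the arrays (median 54.2%), a range that includes 50%, with a median log2 difference of 1.13 where picked and 0.049 where held out. Without those 4 arrays, in 6 against 2, all 150 genes kept their direction, a median of 74.8% of the difference was left and 97 did not move by over 1.5 times, but the genes had been picked with control arrays 1 and 2 among the data, so this decides nothing. The labels give no processing batch or date, so a batch, a difference between donors, pneumoperitoneum and time under anaesthesia stay open as untested.

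At a limma adjusted p under 0.05 the count of genes was 0 (994 at an unadjusted p under 0.05), with a highest other count of 2. The count of lists past camera was also 0 (3 at an unadjusted p under 0.05), with a highest other count of 8. Beside a count of 0 all 100 of 100 splits give at least as many whatever the data, so the splits say nothing about chance for either. At least 1 list passed in 62 of the 99 other splits, so a list that passed in only some of the settings may be no more than such a regrouping gives.

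Of 142 groups of arrays tested for a single far value, 12 had one, where chance gives about 7.1. In each case the gap to the nearest array, as a share of the whole range of the group, was above Dixon's critical value at the 95% level. Of the 12, 9 were in laparoscopic arrays. Array 5 was far from the mean of the other laparoscopic arrays for AGAP1 (share 0.7265, 8.25 against 7.45), ZFP36L1 (0.6454, 6.51 against 7.71), PPARA (0.6288, 6.41 against 7.07), TEK (0.7002, 9.41 against 8.65) and its median signal (0.6408, 127.7 against 111). Array 2 was far from the rest for ZNF292 (0.6519, 6.85 against 7.64), SLC4A4 (0.68, 12.07 against 11.64) and POSTN (0.689, 9.03 against 7.81), and array 1 for HYOU1 (0.6459, 9.60 against 10.25). In the controls, array 1 was far from the rest for CA4 (0.6469, 9.93 against 9.20) and NFIL3 (0.6869, 8.20 against 8.88), and array 4 for CDH5 (0.6849, 6.15 against 6.77).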

How the results depend on the processing

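All alternatives chosen before the data were examined were run; the runs without several arrays, and those with the GAPDH or beta-actin 3'/5' ratio alone or both as 2 covariates, were chosen afterwards. The precision of every value is limited by 6 arrays per group, and signal over background is unknown because no detection calls were used. Except where a value itself shows it, the cause of a change below was not tested. With the replicate number as a block 0 genes passed and 136 were at p under 0.005, and no call changed. The numbers do not pair the donors: deviations of same-numbered arrays correlated at -0.073 to 0.038, 0 of 6 pairs above 0.1, and 1 of the laparoscopic arrays correlated best with its own number. Of the differences of the 66 genes named by the fixed rule over all alternatives, 1810 kept their direction and side of the threshold, 8 newly passed and 10 turned. The genes had been picked by smallest p in these same arrays, which favours a kept direction. Outside the rule KCNN1 also passed in 1 run.

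The number of genes past adjusted p 0.05, 0 as reported, was 2 with a pseudocount of 64 (CDKN1A at 0.032 and OSBPL8 at 0.041), 2 with eBayes with trend and robust (both at 0.0077) and 1 without the 4 arrays of lowest correlation (CR2 at 0.00069). These 4 were laparoscopic arrays 1 and 5 and control arrays 4 and 6. Laparoscopic arrays 1 and 5 had the highest CR2 levels of their group (6.90 and 8.36, the others 4.61 to 5.14), which favours that result. Leaving out single arrays gave 0 to 3, with BARX2 (0.032) without laparoscopic array 3, and CR2, AGAP1 and KCNN1 without laparoscopic array 5. Over all alternatives the adjusted p ranged from 0.0077 to 0.804 for CDKN1A, 0.0077 to 0.954 for OSBPL8 and 0.00069 to 0.954 for CR2. The number at unadjusted p under 0.005, 150 as reported, was 244 with every probe set on its own, where more features were tested. When single arrays were left out it was 98 to 219. Without 1 of control arrays 3 to 6 it was 98 to 104, and without control array 1 or 2 it was 219 or 192. Without 1 of the laparoscopic arrays it was 119 to 135. It was 50 without control arrays 3 to 6 and 63 without the 4 arrays of lowest correlation, with 28 genes shared, both in fewer arrays. With the GAPDH ratio alone it was 68, with the beta-actin ratio alone 140 and with both 42, near the 46.6 expected by chance, where the median SE of the 150 genes grew from 0.21 to 0.35 and the median difference from 0.83 became 0.74. With the mean of the 2 ratios it was 159, but that mean hardly differs between the groups (correlation 0.039), so this run adjusts for little.

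The number of lists past the threshold, 0 as reported, was 2 with median centring (oxidative phosphorylation and ribosomal proteins), 3 without control arrays 3 to 6 (tubular injury, leukocyte, and fibroblast and smooth muscle), and 0 to 4 when single arrays were left out, with 4 without laparoscopic array 2 (tubular injury, oxidative phosphorylation, proximal tubule and thick ascending limb).

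Several list means and the differences of 9 of the 66 genes named by the rule turned their direction, among them differences that were not near 0 (-0.59 for TNF and -0.54 for POSTN as reported). Outside the rule the differences of ADM (-0.090 without laparoscopic array 5), FOS (0.076 without control array 1) and LCN2 (0.038 without laparoscopic array 2) turned as well when single arrays were left out. Without control arrays 3 to 6 the mean was 0.015 for antioxidant defence, -0.055 for acid-base transport, 0.024 for circadian clock and 0.32 for fibroblast and smooth muscle, and the difference was -0.00098 for HSPA5, 0.0014 for SLC4A4 and 0.31 for POSTN. Without the 4 arrays of lowest correlation it was -0.22 for the immediate-early response, -0.19 for NF-kB, -0.016 for acid-base transport, -0.011 for distal tubule and collecting duct, 0.12 for fibroblast and smooth muscle and 0.016 for HLF. Without a filter it was 0.018 for apoptosis and 0.080 for blood, with median centring 0.0087 for fibroblast and smooth muscle, with both 3'/5' ratios 0.095 for TNF, -0.29 for CD3E and -0.57 for FABP4, with the beta-actin ratio alone -0.49 for FABP4, and with the mean of a gene's probe sets -0.021 for RPL7 and -0.094 for LPL. Leaving out single arrays gave -0.048 to 0.17 for NF-kB, -0.025 to 0.038 for the interferon response, -0.033 to 0.018 for apoptosis, -0.0050 to 0.12 for distal tubule and collecting duct, -0.084 to 0.060 for fibroblast and smooth muscle and -0.11 to 0.12 for blood. Of the array measures it gave differences of -3.50 to 1.35 for the median signal, -0.0018 to 0.0073 for the correlation within the group and -0.77 to 0.48 for log2 18S signal. The unadjusted exact permutation p ranged from 0.011 to 0.056 for the beta-actin ratio, from 0.015 to 0.12 for the GAPDH ratio and from 0.015 to 0.15 for the Alu signal.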

Other observations

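The genes in the next 2 paragraphs, the p53 targets named one by one, and the tests of CDKN1A without or with only control arrays 3 to 6 and of nephron segments, were chosen after their values were seen. The other tests were written down beforehand.

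The genes in this paragraph and the next are a selection of those at an unadjusted p under 0.005 outside the lists, and whether genes of their kinds are more frequent there than among all genes was not tested. None of them passed after adjustment (limma adjusted p = 0.256 for each). S100A6, a calcium-binding protein, was 11.43 ± 0.35 in the laparoscopic and 10.60 ± 0.40 in the control kidneys, and ANXA6, a membrane-binding annexin, differed by 0.73 (SE 0.18). Without control arrays 3 to 6 these 2 differences were 0.76 and 0.65. PIGR, the epithelial transporter of polymeric immunoglobulin, was higher by 1.01 (SE 0.25), and this difference was 0.28 without those arrays. The glucose transporter SLC5A1 and the sialyltransferase ST6GAL1 were higher by 0.90 (SE 0.23) and 0.96 (SE 0.24), and without those arrays by 0.49 and 1.32.

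Lower in the laparoscopic kidneys were CLDN8, a tight junction protein of the distal nephron, by -0.66 (SE 0.17), and COL4A3, a collagen chain of the glomerular basement membrane, by -0.98 (SE 0.25), and these differences were -0.53 and -0.52 without control arrays 3 to 6. Of the other probe sets of COL4A3, 4 of 6 had the same direction. TNFRSF11B, the decoy receptor osteoprotegerin, was 6.74 ± 1.21 against 8.40 ± 0.17, a difference of -1.66 (SE 0.44), and -1.76 without those arrays, with its other probe set in the opposite direction. The transcriptional regulators YY1 and KDM5A were lower by -0.81 (SE 0.19) and -1.05 (SE 0.26), and these differences were -0.38 and -0.46 without them.

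The higher CDKN1A level (1.41 on the log2 scale) is a pattern with several candidate explanations. Without control arrays 3 to 6 the difference was 1.91 (95% confidence interval 1.34 to 2.48). In 20 choices of 3 laparoscopic arrays against only those 4 its limma p was under 0.005 each time. It was never the smallest among higher genes (rank 2 to 29), so CDKN1A was picked with the help of control arrays 1 and 2. In the held-out arrays, the 3 other laparoscopic against control arrays 1 and 2, the difference was 1.662 to 2.155. Control arrays 3 to 6 had levels of 8.05 to 8.57, nearer to the laparoscopic arrays than control arrays 1 and 2 (7.89 and 7.37). Those 4 arrays thus made the difference smaller, which argues against them as its only source. Because of how CDKN1A was picked, its difference against control arrays 1 and 2 may be overstated. A p53 response that raises its targets as a group by 0.705, 50% of the CDKN1A difference, is argued against by their list. Over 16 genes the camera p was 0.704 and the mean difference -0.010 (95% confidence interval -0.132 to 0.112), which excludes 0.705. A smaller rise, within that interval, is not excluded. Some targets, such as MDM2 (6.31 and 6.07) and PPM1D (6.64 and 6.76), lay below the median of all probe sets (7.02). Single targets went both ways, with TP53I3 higher by 0.44 (SE 0.14, unadjusted p = 0.0082), SESN1 higher by 0.35 (SE 0.16) and BAX lower by -0.78 (SE 0.32); BAX, FAS and TNFRSF10B are also in the apoptosis list and GDF15 in that of tubular injury. Chance among the genes tested stays open, because 27 of 100 splits of the arrays gave a smallest p as low as that of CDKN1A, and so do pneumoperitoneum and time under anaesthesia, which the design does not separate.

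Proximal tubule markers were lower and thick ascending limb markers higher, though neither list passed (camera adjusted p = 0.183 for both) and both 95% confidence intervals included 0 (-0.286 to 0.045 and -0.204 to 1.01). The 2 means were -0.060 and 0.42 with median centring, and -0.15 and 0.096 without control arrays 3 to 6. If real, the opposite shifts may reflect a smaller share of proximal tubule in the laparoscopic cores. Such a share would raise the markers of all other segments and cells alike. The podocyte, endothelium and fibroblast means were not raised (-0.10, -0.083 and -0.0078), whereas the distal and leukocyte means were 0.050 and 0.18. Each of these 95% confidence intervals included 0, so a small rise in them is not excluded. The thick ascending limb list exceeded the podocyte list by 1.70 SE, the endothelium list by 1.89, the distal list by 1.42, the fibroblast list by 1.23 and the leukocyte list by 0.71, too little to decide, so a different make-up of the cores cannot be told apart from a change within tubule cells. A response of the thick ascending limb itself to surgery or diuresis was not tested.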
